A study of Mus musculus with 6 samples.

How the data were processed

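RNA-seq was done on 6 libraries of sorted leukaemic granulocyte-macrophage progenitors from C57BL/6 mice, 3 WT and 3 KO, the latter labelled as carrying knockouts of Prkaa1 and Prkaa2. Per the labels' protocols, cells were sorted into Trizol, RNA was purified on columns, cDNA was made by Smart-seq2 and libraries were made with Nextera XT and sequenced on a NextSeq 500. The labels name neither the oncogene that drives the leukaemia, nor the number of mice, nor a batch.

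Per the submitters' processing notes, reads were handled with CASAVA and bcl2fastq, aligned to mm10 with STAR 2.5.3a, and processed with DESeq2 1.18.1. The authors deposited 1 table of FPKM values, read numbers scaled by gene length and library size, for 47643 Ensembl gene IDs and symbols in the 6 libraries. The read counter, its annotation, its strand setting and the treatment of multimapped reads are not given in the sources used here. Of these genes, 21132 were above 0 in at least 1 library and 26511 were at 0 in all 6. Symbols were taken as deposited, 118 of them being carried by more than 1 ID.

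Whole reads were recovered from the FPKM values by dividing each by the library's smallest step for the gene's length. They came out whole within a tolerance of 0.001 for 97.6% of the genes above 0: 16481 at the exonic length of the annotation and 4134 at a length searched for, where the read number is the smallest that the values allow (of the genes given a floor or read ratio, Hpgd, Calml4, Agpat3, Hist1h1a and Prss34). The other 517 genes have no read number. These reads gave the depths in the report, the floors, the counting intervals and 1 alternative, and were not used for the main test. The library denominators implied by the deposited FPKM values are proportional to median-ratio size factors computed from the recovered reads. Positions, gene types, GC content and exon overlaps came from the GENCODE M21 annotation and the GRCm38 (mm10) genome, which held 47224 of the IDs (99.1%). Of the 212 genes named by rule, 75 share exonic bases with another gene, and 8 share more than 20% of them: Ly6k (47.6%), Prkag1 (43.7%), Acadvl (42.9%), Ctsd (34.4%), Naa60 (26.3%), Ube2c (22.8%), Cebpb (20.7%) and Hoxa7 (20.4%). Such genes are uncertain, because the strand setting of the counting is not stated.

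Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) in limma 3.58.1 under R 4.3.3. The fit used a linear model of genotype and empirical Bayes moderation with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment over 9108 genes at a threshold of 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Where a group had no read, its fold is a lower bound against 3 reads over the group, and where it had 1 to 3 reads, the read ratio has a 95% exact counting interval. Both cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The test was tried on simulated data: noise at 2.99 times Poisson variance was drawn for the 9108 genes of the comparison, with 50 genes each changed by 1.25, 1.5, 2 and 4-fold. Of these, 30, 64, 78 and 92% were recovered. There, 10 unchanged genes were called, 7.04% of all calls.

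The gene lists, the main test, the rule for named genes and most alternatives were set before the data were examined. The 53 lists were written from general knowledge and hold 1345 entries, 1339 of them in the table, some in more than 1 list. They cover AMPK subunits, AMPK upstream kinases and direct substrates, acetyl-CoA production and transport, BET proteins and elongation factors, histone acetyltransferases, histone deacetylases and sirtuins, the MLL-fusion and self-renewal programme, BET-dependent genes of myeloid leukaemia, and haematopoietic transcription factors. For metabolism they cover glucose uptake and glycolysis, the pentose phosphate pathway, the tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, mitochondrial biogenesis, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, and one-carbon, serine and nucleotide synthesis. For stress and growth they cover autophagy and lysosome, the integrated stress response, the unfolded protein response, heat shock, NRF2, p53 and FOXO targets, hypoxia, mTORC1 signalling, S phase, G2 and M phase, MYC targets, cytosolic ribosomal proteins, replication-dependent histones, immediate-early genes, nuclear-retained RNA, sex-linked transcripts and the BCL2 family. Immune lists were interferon-stimulated genes, NF-kB and cytokines, and MHC class II. Cell type lists were progenitor granule genes, neutrophil maturation, monocytes, haematopoietic stem cells, erythroid cells, megakaryocytes, T cells, B cells, natural killer cells, basophils with mast cells and eosinophils, dendritic, endothelial and stromal cells. Lists with at least 5 measured members were tested by camera with a preset inter-gene correlation of 0.01 and adjusted over the 45 tested lists, and camera with an estimated correlation and fry were run as alternatives.

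Genes were named by rule: all AMPK subunits and fixed genes (Myc, Myb, Bcl2, Cdk6, Hoxa9, Meis1, Brd2, Brd3, Acly, Acss2, Hexim1 and Slc2a1), the 10 largest changes of log2(FPKM + 1) in each direction among called genes with curated symbols whose genotypes do not overlap, and up to 4 members per list with the smallest p. Some genes that the rule takes in are not reported here. Other members, named where 5 or fewer stood apart from their list, and the mature neutrophil transcripts, Hoxa5 and Ftl1 were chosen after their values were seen. The alternatives planned were pseudocounts of 0.1 and 0.5, no filter and minimum means of 0.1 and 5 FPKM, rescaling of all libraries to equal sums (the TPM scale), median-ratio scaling, quantile and cyclic loess normalization, 3 other variance models, a replicate block, and leaving out each library in turn. A correction for GC content and gene length, that correction with the replicate block, and voom on the recovered reads were added after seeing the data. Protein, metabolite or chromatin data were not analysed here.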

Results

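The data were RNA-seq libraries of leukaemic granulocyte-macrophage progenitors (L-GMP), leukaemia cells that resemble the normal progenitor of granulocytes and monocytes, sorted from C57BL/6 mice. Of the 6 libraries, 3 came from wild-type (WT) cells and 3 from cells labelled as knockout (KO) for Prkaa1 and Prkaa2, the genes of the catalytic subunits of AMP-activated protein kinase (AMPK), which senses low cellular energy. The series title places AMPK between the supply of acetyl-CoA and the recruitment of BET proteins, readers of acetylated histones, in acute myeloid leukaemia. The single comparison asks which transcripts differ between KO and WT. Whole reads recovered from the deposited FPKM values came to 11390439, 16416043 and 12897775 in WT and 13872806, 12372361 and 14025446 in KO. Genes above 0 numbered 15956, 16466 and 16104 in WT and 14691, 14560 and 14660 in KO. The values below are FPKM as mean ± SD (n = 3 libraries per genotype), and folds are ratios of those means. Log2 fold changes are differences of log2(FPKM + 1), a scale that understates the change of weakly expressed genes. A gene is called higher or lower, risen or fallen only where the limma adjusted p was under 0.05. A median called rescaled is that of libraries rescaled to equal sums, where the median of all genes was -0.45. That rescaling raised the values of every library before the 1 was added, so the added 1 weighs less there.

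Prkaa1 RNA was lower in each KO library than in any WT library: 2.01, 2.20 and 1.80 FPKM in WT replicates 1, 2 and 3, and 1.11, 0.735 and 0.548 in KO replicates 1, 2 and 3. The KO mean was 39.8% of the WT mean (log2 fold change -0.75, SE 0.13, limma adjusted p = 0.00112), from 422 reads in WT and 138 in KO. Prkaa2 was almost unread in both genotypes, at 0, 0 and 0.0178 FPKM in the WT replicates and 0, 0.0220 and 0.0194 in the KO replicates, or 2 reads against 4. Its read ratio of KO to WT was 2.42 with a 95% counting interval of 0.347 to 26.7 (exact permutation p = 0.400), so a loss of Prkaa2 was not detectable at this depth. Prkaa1 (ENSMUSG00000050697) lies at mm10 chromosome 15, 5143861 to 5181899, plus strand, and Prkaa2 (ENSMUSG00000028518) at chromosome 4, 105029874 to 105109890, minus strand. The labels do not name the deleted exons, and the values per gene sum all exons. RNA that remains need not therefore encode an active subunit. Among the regulatory subunits, Prkab1 fell from 20.9 ± 1.21 to 15.3 ± 0.427 FPKM (adjusted p = 0.000212) and Prkag1 rose from 70.1 ± 0.986 to 113 ± 3.33 FPKM (adjusted p = 6.99e-07). Prkag1 is uncertain because 43.7% of its exonic bases overlap another gene. Prkab2 (from 0.158 FPKM in WT to 0.0585 in KO), Prkag2 (0.819 and 0.837) and Prkag3 (0 and 0.00700) lay under the minimum mean of 1 FPKM and were not tested. With libraries rescaled to equal sums, the log2 change of Prkag2 was -0.27, against a median of -0.45 for all genes. As a list, the subunits had 3 measured members, too few for the list test.

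**Figure D1:**
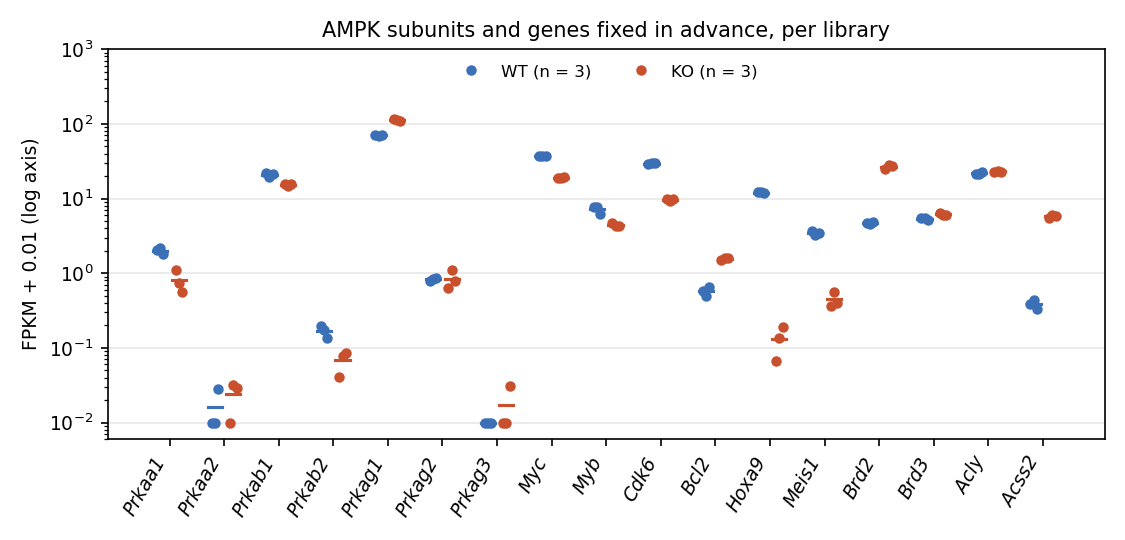
FPKM plus 0.01 on a log axis for the 7 AMPK subunit genes and 10 other genes chosen in advance, 1 point per library (3 WT, 3 KO) and a bar at each genotype's mean. Prkaa1 was lower in every KO library than in any WT library, and Prkaa2 stayed at or below 0.0220 FPKM in all 6. Brd3, slightly higher in KO here, and Acly, without a call here, are lower in KO once each library is rescaled to equal sums.

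S100a8 and S100a9, calcium-binding proteins of neutrophils and monocytes, rose from 205 ± 6.71 to 52072 ± 617 FPKM and from 67.7 ± 1.98 to 14559.7 ± 71.9 FPKM, or 254-fold and 215-fold. Ngp (neutrophilic granule protein) rose 465-fold to 4568 FPKM. Ltf (lactotransferrin) rose 1614-fold to 155 FPKM. Prg2, the major basic protein of eosinophil granules, had 1 read in WT and 9305 in KO (ratio 11255-fold, interval 2019.5 to 444587). Ldhb, a lactate dehydrogenase subunit, had 2 reads against 8597 (5199-fold, interval 1439 to 42938). Rab38, a small GTPase, had no read in WT and was at least 1347-fold higher in KO. Rps4l (2834-fold, interval 508 to 111982), Cited4 (130.0-fold) and Ifitm6 (60.9-fold) complete the 10 largest rises on the log2(FPKM + 1) scale, which ranks abundant genes above scarcer ones with larger folds. On the log2(FPKM + 1) scale, by which these genes were ranked, the largest fall was that of Ly6k, a surface antigen, from 13806 reads in WT to 1 in KO (WT over KO 11414-fold, interval 2048 to 450872). Hpgd, which degrades prostaglandins (12337-fold, interval 2214 to 487315), and Serpinf1, a secreted serpin (6299.9-fold, interval 1130.4 to 248866), were also left with 1 read each in KO. Cth, the cystathionine lyase that makes cysteine, was at least 1144-fold lower in KO, Gtsf1 at least 571-fold and Calml4 at least 304-fold, all 3 without a read in KO. Stfa1 (a stefin, 105-fold lower), Hoxa7 (185-fold), Cox6a2 (95.8-fold) and Mgmt, a DNA repair enzyme (45.7-fold), complete the 10 largest falls on that scale. Stfa1 and Rps4l share sequence with near-identical copies and are uncertain, as is Ly6k, with 47.6% of its exonic bases shared with another gene. S100a8 and S100a9 lie at chromosome 3, 90668978 to 90670035, plus strand, and chromosome 3, 90692632 to 90695721, minus strand.

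**Figure D2:**
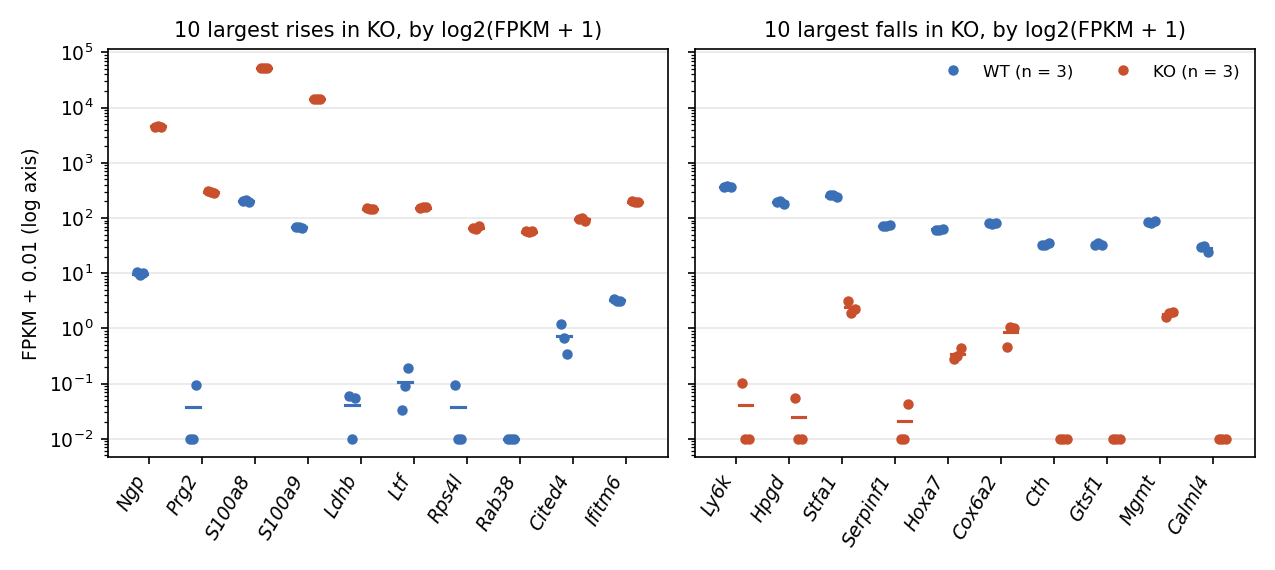
FPKM plus 0.01 on a log axis for the 10 genes with the largest rise in KO (left) and the 10 with the largest fall (right) on the log2(FPKM + 1) scale, 1 point per library (3 WT, 3 KO) and a bar at each genotype's mean. The genes were chosen among called genes whose genotypes do not overlap. S100a8 reached a mean of 52072 FPKM in KO.

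Of 9108 genes tested by limma-trend, 3464 were higher in KO, 3676 were lower and 1968 did not pass. On the log2(FPKM + 1) scale, at least a 2-fold change was seen in 1168 of the higher and 1242 of the lower genes, and at least a 4-fold change in 302 and 307. The 3 KO values lay wholly above or below the 3 WT values in 7344 genes (80.6%), where chance alone gives 10%. The direction split depends on scaling: 48.5% of called genes were higher as deposited, but 27.8% (2069 higher, 5376 lower) once each library was rescaled to equal sums, which shifted the median log2 change of all genes from -0.02 to -0.45. The FPKM values of a KO library sum to more (650199, 653819 and 649611, against 463683, 470734 and 475654 in WT). The 10 most abundant genes take 17.1, 17.5 and 17.4% of recovered reads in KO against 5.61, 5.64 and 5.76% in WT. S100a8 took 3.30 to 3.37% of KO reads. Nothing in the labels says that replicates came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. For a single gene, an exact permutation test of 3 against 3 libraries cannot give a p below 0.1.

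The HOXA part of the self-renewal programme known from leukaemia with MLL fusions was nearly gone from the KO libraries. Hoxa7 fell from 62.2 ± 1.95 to 0.336 ± 0.0834 FPKM (log2 fold change -5.57, SE 0.06) and Hoxa9 from 12.0 ± 0.253 to 0.121 ± 0.0622 FPKM (-3.54, SE 0.07, adjusted p = 2.14e-08). Hoxa7 shares 20.4% of its exonic bases with another gene. Hoxa10 had 10.2 ± 0.121 FPKM in WT and no read in KO, at least 414-fold lower. Meis1, the partner of HOXA9, fell 7.94-fold from 3.45 ± 0.232 to 0.434 ± 0.108 FPKM (adjusted p = 2.12e-06). The neighbouring Hoxa7, Hoxa9 and Hoxa10 lie on chromosome 6 between 52214491 and 52240854 on the minus strand. Cdk6, a cell cycle kinase, fell 3.05-fold from 29.4 ± 0.530 to 9.66 ± 0.368 FPKM (adjusted p = 9.51e-08), Myc 1.95-fold from 37.3 ± 0.475 to 19.1 ± 0.294 FPKM (adjusted p = 2.67e-07) and Myb 1.64-fold from 7.23 ± 0.814 to 4.41 ± 0.221 FPKM (adjusted p = 0.000464). Of the programme's 18 measured genes, 13 fell, 4 rose (Psip1, Men1, Bcl2 and Dot1l) and 1 (Jmjd1c) did not pass, with 4 up and 13 down adjusted over the list alone (median log2 change -1.50, camera adjusted p = 0.00827, and adjusted p = 0.112 with an estimated correlation). With libraries rescaled to equal sums, its median was -2.07, against -0.45 for all genes. Its adjusted p was then 0.0821, so the call was lost although the median lay lower (range over 24 alternatives 1.64e-08 to 0.112). The shift of all genes and the lighter weight of the added 1 both enter that lower median. Bcl2, an inhibitor of cell death, rose 2.74-fold from 0.570 ± 0.0840 to 1.56 ± 0.0599 FPKM (adjusted p = 0.000121).

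Genes listed from general knowledge as BET-dependent in myeloid leukaemia went both ways, most of them upward. Their dependence on BET proteins was not tested here. Cebpb, Irf8, Ccnd3 and E2f2, regulators of myeloid differentiation and of the cell cycle, rose 6.98-fold, 5.09-fold, 2.09-fold and 6.61-fold. Cebpb shares 20.7% of its exonic bases with another gene. Cdk6, Myc and Myb, in the same list, fell as above. In all, 15 of 21 measured members rose, 6 fell and 0 did not pass the test, with 15 up and 6 down adjusted over the list alone (median log2 change 0.71, rescaled 0.59, camera adjusted p = 0.0300, and adjusted p = 0.215 with an estimated correlation). A minimum mean of 5 FPKM in place of 1 gave a median of 0.44 and an adjusted p of 0.217 and lost the call (range over 24 alternatives 1.71e-06 to 0.217). Among haematopoietic transcription factors, 22 of 28 measured members rose, 6 fell and 0 did not pass the test, with 22 up and 6 down adjusted over the list alone (median log2 change 0.91, rescaled 0.57, camera adjusted p = 0.00114, and adjusted p = 0.0799 with an estimated correlation). These factors share Cebpb, Irf8 and Myb, among other genes, with the BET-dependent list, so the rises of these lists are not independent. Id1, an inhibitor of differentiation, rose from 62.6 ± 2.61 to 722 ± 12.5 FPKM and Cebpd from 36.6 ± 1.60 to 173 ± 6.89 FPKM. Gata1, the master factor of erythroid, mast cell and megakaryocyte development, had no read in WT and 18.7 ± 0.498 FPKM in KO, at least 685-fold higher.

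Genes of neutrophil maturation formed a strongly raised group in KO. Beside S100a8, S100a9 and Ngp, Lyz2 (lysozyme) rose 36.1-fold from 273 ± 3.69 to 9869.7 ± 389 FPKM. Of its 24 measured members, 19 rose and 5 fell (Trem3, Stfa1, BC100530, Ncf1 and Padi4), with 19 up and 5 down adjusted over the list alone (median log2 change 2.32, rescaled 2.40, camera adjusted p = 2.01e-05, and adjusted p = 0.0583 with an estimated correlation). Markers of basophils, mast cells and eosinophils moved with them: 9 of 9 measured members rose, 9 adjusted over the list alone (median log2 change 2.78, rescaled 3.33, camera adjusted p = 5.38e-05, and adjusted p = 0.0672 with an estimated correlation). Their median was 5.62 with the 4 members without a WT read set at their lower bound. Prss34, a protease of basophils and mast cells, had no WT read and was at least 539.9-fold higher. Cpa3 (carboxypeptidase of mast cells) rose 23.3-fold to 24.8 FPKM and Hdc, which makes histamine, 8.17-fold to 25.8 FPKM. Among erythroid genes, 8 of 9 measured members rose, 0 fell and 1 did not pass the test (Tfrc), with 8 up and 0 down adjusted over the list alone (median log2 change 1.87, rescaled 1.77, camera adjusted p = 0.00196, and adjusted p = 0.101 with an estimated correlation). Blvrb (a haem catabolism enzyme) rose 10-fold, Klf1 12.8-fold and Car2 (carbonic anhydrase) in the ratio 2015-fold, interval 361 to 79639. Summed over all 22 erythroid members, whether tested or not, expression was 39.9 FPKM in WT and 245 in KO, and over the 25 members of the basophil, mast cell and eosinophil list 35.9 and 597. Of the 22, 6 lay at 1 FPKM or more in WT and 9 in KO, and of the 25, 4 and 11. Members could thus pass the minimum mean of 1 FPKM through their KO values alone, which favours rises among the measured members of both lists. In the list of granule and other genes of normal granulocyte-monocyte progenitors, the granule genes Elane, Prtn3 and Mpo rose 4.51-fold, 4.35-fold and 2.77-fold. Clec12a, in the list but not a granule gene, had no read in KO and was at least 920.5-fold lower. The list of 15 had no call (9 rose, 6 fell, adjusted p = 0.275, median 0.55, rescaled 0.18).

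Genes of ribosome production fell together. Npm1 and Ncl, nucleolar proteins, fell 2.29-fold and 3.68-fold, Srm (spermidine synthase) fell 4.24-fold from 749.9 ± 33.0 to 177 ± 6.69 FPKM, and Wdr74 fell 2.40-fold. Of 44 MYC target and ribosome biogenesis genes, 43 fell, 0 rose and 1 (Odc1) did not pass, with 0 up and 43 down adjusted over the list alone (median log2 change -1.42, rescaled -1.92, camera adjusted p = 2.49e-12, and adjusted p = 0.0583 with an estimated correlation). Among cytosolic ribosomal proteins, 63 of 66 fell, 2 rose (Rps2 and Rplp0, both lower with libraries rescaled to equal sums) and 1 (Rps20) did not pass, with 2 up and 63 down adjusted over the list alone (median log2 change -0.66, rescaled -1.13, camera adjusted p = 4.43e-14, and adjusted p = 0.224 with an estimated correlation). Rps15 fell 1.98-fold, Rpl12 3.12-fold and Rpl4 1.86-fold. Reads of this family are uncertain because its many processed pseudogenes share sequence with it.

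Enzymes of serine, folate and nucleotide synthesis fell as well: Shmt2 2.85-fold from 421 ± 10.4 to 148 ± 5.05 FPKM, Psat1 2.86-fold and Mthfd1 4.96-fold. Rrm2, a ribonucleotide reductase subunit, went the other way, 2.59-fold up. Of 26 one-carbon, serine and nucleotide synthesis genes, 22 fell and 4 rose (Rrm2, Impdh1, Tyms and Tk1, the last 2 lower with libraries rescaled to equal sums), with 4 up and 22 down adjusted over the list alone (median log2 change -0.96, rescaled -1.43, camera adjusted p = 0.000269, and adjusted p = 0.0672 with an estimated correlation). The integrated stress response, the programme of ATF4, shares Psat1 and Shmt2 with that list. Its Eif4ebp1 and Asns (asparagine synthetase) fell 2.29-fold and 2.14-fold. Of its 23 members 15 fell, 6 rose and 2 did not pass, with 6 up and 15 down adjusted over the list alone (median log2 change -0.89, rescaled -1.36, camera adjusted p = 0.0189, and adjusted p = 0.113 with an estimated correlation). Heat shock genes fell in 12 of 14 cases and rose in 2 (Dnajb1 and Hsf1, the latter lower with libraries rescaled to equal sums), with 2 up and 12 down adjusted over the list alone (median log2 change -0.65, rescaled -1.12, camera adjusted p = 0.00339, and adjusted p = 0.101 with an estimated correlation). The mitochondrial chaperones Hspd1 and Hspe1 fell 3.88-fold and 2.73-fold, Fkbp4 2.59-fold and Chordc1 2.89-fold. Of S phase genes, 7 of 41 measured members rose, 28 fell and 6 did not pass the test, with 7 up and 28 down adjusted over the list alone (median log2 change -0.32, rescaled -0.79, camera adjusted p = 0.0248, and adjusted p = 0.113 with an estimated correlation). Mcm2, of the replicative helicase, fell 1.90-fold, Uhrf1 2.04-fold and Rfc4 1.32-fold. The S phase call was lost at a minimum mean of 5 FPKM (median -0.31, adjusted p = 0.0791) and with cyclic loess normalization (median -0.29, adjusted p = 0.0663), with medians close to the reported one, in a range over the alternatives of 1.28e-05 to 0.113.

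Genes of the NRF2 antioxidant response and of ferritin rose. Nqo1, a quinone reductase, rose 17.7-fold from 36.1 ± 2.36 to 638 ± 6.48 FPKM. The peroxiredoxins Prdx1 and Prdx5 rose 4.63-fold and 3.86-fold, and Fth1, the ferritin heavy chain, 2.68-fold from 5142 ± 55.6 to 13772 ± 82.2 FPKM (the Fth1 call is lost with quantile normalization). In this list 23 of 28 measured members rose, 2 fell and 3 did not pass the test, with 24 up and 2 down adjusted over the list alone, and the members that fell were Prdx3 and Slc7a11 (median log2 change 1.34, rescaled 0.87, camera adjusted p = 6.55e-08, and adjusted p = 0.0583 with an estimated correlation). The ferritin light chain gene Ftl1, chosen after its values were seen, took 1.61 to 1.71% of recovered reads in WT libraries and 7.57 to 7.83% in KO libraries. Its count is uncertain because it has near-identical copies. Autophagy and lysosome genes rose together: Psap (prosaposin) 6.59-fold from 62.8 ± 2.26 to 414 ± 3.61 FPKM, Map1lc3a, of the LC3 family that coats autophagosomes, 6.49-fold, and the cathepsins Ctsd and Ctsb 2.83-fold and 2.38-fold. In all, 36 of 42 measured members rose, 2 fell and 4 did not pass the test, with 36 up and 2 down adjusted over the list alone (median log2 change 0.58, rescaled 0.22, camera adjusted p = 3.59e-07, and adjusted p = 0.0583 with an estimated correlation). Ctsd is uncertain, since 34.4% of its exonic bases overlap another gene. FOXO targets rose in 11 of 14 cases, fell in 1 and did not pass in 2, with 11 up and 1 down adjusted over the list alone (median log2 change 1.80, rescaled 1.54, camera adjusted p = 0.00271, and adjusted p = 0.101 with an estimated correlation). Txnip, an arrestin induced by glucose, rose 8.10-fold, Klf6 3.69-fold, Cited2 4.55-fold and S1pr1 in the ratio 487-fold, interval 135 to 4032. A minimum mean of 5 FPKM gave the FOXO list a median of 0.89 and an adjusted p of 0.0931 and lost its call (range over the alternatives 7.87e-08 to 0.101).

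Among fatty acid synthesis genes, Dgat1 and Dgat2, which catalyse the last step of triglyceride synthesis, rose 3.57-fold and 5.07-fold, and Tecr rose 1.39-fold (a call lost with libraries rescaled to equal sums). Agpat3, an acyltransferase, fell from 1984 to 2 reads (820.1-fold, interval 227 to 6777). Of 20 measured members 15 rose, 4 fell (Agpat3, Oxsm, Elovl6 and Fasn) and 1 (Acly) did not pass, with 15 up and 4 down adjusted over the list alone (median log2 change 0.51, rescaled 0.13, camera adjusted p = 0.00785, and adjusted p = 0.112 with an estimated correlation). Transcripts of the mitochondrial genome were higher as deposited (mt-Cytb 1.77-fold, mt-Rnr2 2.22-fold, mt-Nd4 1.85-fold), but their median turned to -0.17 and mt-Co1 (1.27-fold as deposited) turned lower with libraries rescaled to equal sums. Of 10 measured, 7 rose and 3 did not pass (mt-Nd1, mt-Nd2 and mt-Rnr1), with 7 up and 0 down adjusted over the list alone (median log2 change 0.29, camera adjusted p = 0.0291, and adjusted p = 0.562 with an estimated correlation). The call was lost with that rescaling (adjusted p = 0.451), with quantile normalization (median 0.23, adjusted p = 0.19) and with cyclic loess (median 0.29, adjusted p = 0.0663), in a range of 0.000702 to 0.562. Nuclear-encoded oxidative phosphorylation genes had a small shift that scaling reverses: 42 of 75 measured members rose, 26 fell and 7 did not pass the test, with 42 up and 26 down adjusted over the list alone (median log2 change 0.12, camera adjusted p = 0.0475, and adjusted p = 0.598 with an estimated correlation). With libraries rescaled to equal sums, however, the list was lower (median -0.35, adjusted p = 0.00864). Cox6a1, Ndufa1 and Uqcrh, of complexes IV, I and III, rose 1.76-fold, 1.91-fold and 1.60-fold, and Atp5g1, of the ATP synthase, fell 2.35-fold. That list's adjusted p was 0.0669 without WT replicate 1 and 0.0546 without KO replicate 2, which ended the call, and so did quantile (median 0.04, adjusted p = 0.543) and cyclic loess normalization (median 0.11, adjusted p = 0.12), in a range over the alternatives of 0.000611 to 0.598.

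Replication-dependent histone genes rose in KO: Hist1h1c 32.7-fold from 5.46 ± 0.404 to 179 ± 6.61 FPKM, Hist1h2bc 26.5-fold, Hist1h4i 5.94-fold and Hist1h1a in the ratio 107-fold, interval 29.2 to 891. In this family 20 of 22 members rose and 2 did not pass (Hist1h3c and Hist1h2ak), with 20 up and 0 down adjusted over the list alone (median log2 change 1.43, rescaled 1.22, camera adjusted p = 1.39e-05, and adjusted p = 0.0583 with an estimated correlation). Its genes are near-identical in sequence, so reads of single members are uncertain, and most of their mRNA lacks the poly(A) tail by which Smart-seq2 primes. Immediate-early genes, which also respond to cell dissociation, rose in 14 of 19 cases, fell in 3 (Fosl1, Dusp2 and Dusp1) and did not pass in 2, with 14 up and 3 down adjusted over the list alone (median log2 change 1.49, rescaled 1.03, camera adjusted p = 0.00225, and adjusted p = 0.113 with an estimated correlation). Ier3 rose 18.6-fold to 265 FPKM, Fos 8.6-fold and Ier2 2.83-fold. The list of nuclear-retained and unprocessed RNA rose in 5 of 6 members, with 5 up and 0 down adjusted over the list alone (median log2 change 1.13, rescaled 1.07, camera adjusted p = 0.00785, and adjusted p = 0.113 with an estimated correlation). Malat1 rose 7.87-fold from 22.6 ± 1.88 to 178 ± 5.49 FPKM, Rn7sk, which lacks a poly(A) tail, 6.15-fold and Neat1 31.3-fold. Lars2, in the list but a protein-coding gene, rose 1.73-fold. Xist, the RNA of the inactive X chromosome and so of female cells, was present in both genotypes at 3.51 ± 0.280 FPKM in WT and 3.98 ± 0.200 in KO (adjusted p = 0.116), slightly lower in KO with libraries rescaled to equal sums (log2 change -0.25, adjusted p = 0.0315) and called higher with the GC and length correction (0.30, adjusted p = 0.00482) and with voom (0.18, adjusted p = 0.0149). These RNA classes and stress genes differed between genotypes together with the gene groups above.

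The genes that the series title points to changed singly more than as groups. Since 7140 of the 9108 genes tested were called, a call for a single gene does not set it apart. Brd2, a BET protein, rose 5.66-fold from 4.70 ± 0.109 to 26.6 ± 1.62 FPKM (log2 fold change 2.28, SE 0.06, adjusted p = 4.94e-08). Brd3 went from 5.33 ± 0.137 to 6.11 ± 0.190 FPKM (adjusted p = 0.0301), but was lower in KO with libraries rescaled to equal sums (log2 change -0.25, adjusted p = 0.00846). Its call was also lost with the GC and length correction (adjusted p = 0.0510) and without any 1 of 5 libraries (0.0584 to 0.0898). Hexim1, a repressor of transcription elongation whose RNA is a marker of BET inhibition, rose 2.09-fold from 1.82 ± 0.0888 to 3.8 ± 0.0741 FPKM (adjusted p = 2.82e-05). Among BET proteins and elongation factors 13 of 25 measured members rose, 6 fell and 6 did not pass the test, with 13 up and 6 down adjusted over the list alone, Paf1 rising 1.70-fold and Larp7 falling 1.43-fold. That list had no call (adjusted p = 0.248, median 0.17, turning to -0.16 with libraries rescaled to equal sums). Acss2, which makes acetyl-CoA from acetate, rose 15.5-fold from 0.372 ± 0.0516 to 5.78 ± 0.257 FPKM (log2 fold change 2.31, SE 0.07, adjusted p = 1.46e-07). Acly, which makes it from citrate, stood at 21.9 ± 0.886 FPKM in WT and 23.1 ± 0.400 in KO (adjusted p = 0.169), and was lower in KO with libraries rescaled to equal sums (log2 change -0.39, adjusted p = 7.37e-05). It was called higher with quantile (0.12, adjusted p = 0.0441) and cyclic loess normalization (0.17, adjusted p = 0.00775). Mpc2, of the mitochondrial pyruvate carrier, and Crat, a carnitine acetyltransferase, rose 3.58-fold and 3.62-fold, and Pdha1, of pyruvate dehydrogenase, fell 2.16-fold. In the acetyl-CoA list 10 of 19 measured members rose, 7 fell and 2 did not pass the test, with 10 up and 7 down adjusted over the list alone. It had no call (adjusted p = 0.351, median 0.16, turning to -0.31 with the rescaling). Slc2a1, the glucose transporter GLUT1, rose 1.55-fold from 20.4 ± 0.835 to 31.6 ± 2.24 FPKM (adjusted p = 4.91e-05). Of AMPK's upstream kinases and substrates 10 of 17 measured members rose, 0 fell and 7 did not pass the test, with 10 up and 0 down adjusted over the list alone. The list's median was 0.41, but 0.06 with libraries rescaled to equal sums and 0.25 with the GC and length correction. Its adjusted p of 0.0513 missed the threshold, with a range over the alternatives of 4.04e-05 to 0.390 (Tbc1d1 2.78-fold, Stk11 1.58-fold, Map3k7 3.90-fold, Strada 2.04-fold). Histone acetyltransferases split evenly (5 up with Ncoa3 3.0-fold, 5 down with Kat2a 2.46-fold, Kat8 1.51-fold and Naa60 2.08-fold, and 2 not passing, adjusted p = 0.777, median 0.12, turning to -0.30 with the rescaling). Of deacetylases and sirtuins 6 rose (Hdac3 1.97-fold, Sirt7 2.0-fold), 4 fell (Sirt6 2.58-fold, Sirt5 12.2-fold, Hdac8 and Hdac2) and 3 did not pass, with no call (adjusted p = 0.591). Its median was 0.21, its mean -0.06, and the median turned to -0.26 with the rescaling.

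**Figure D3:**
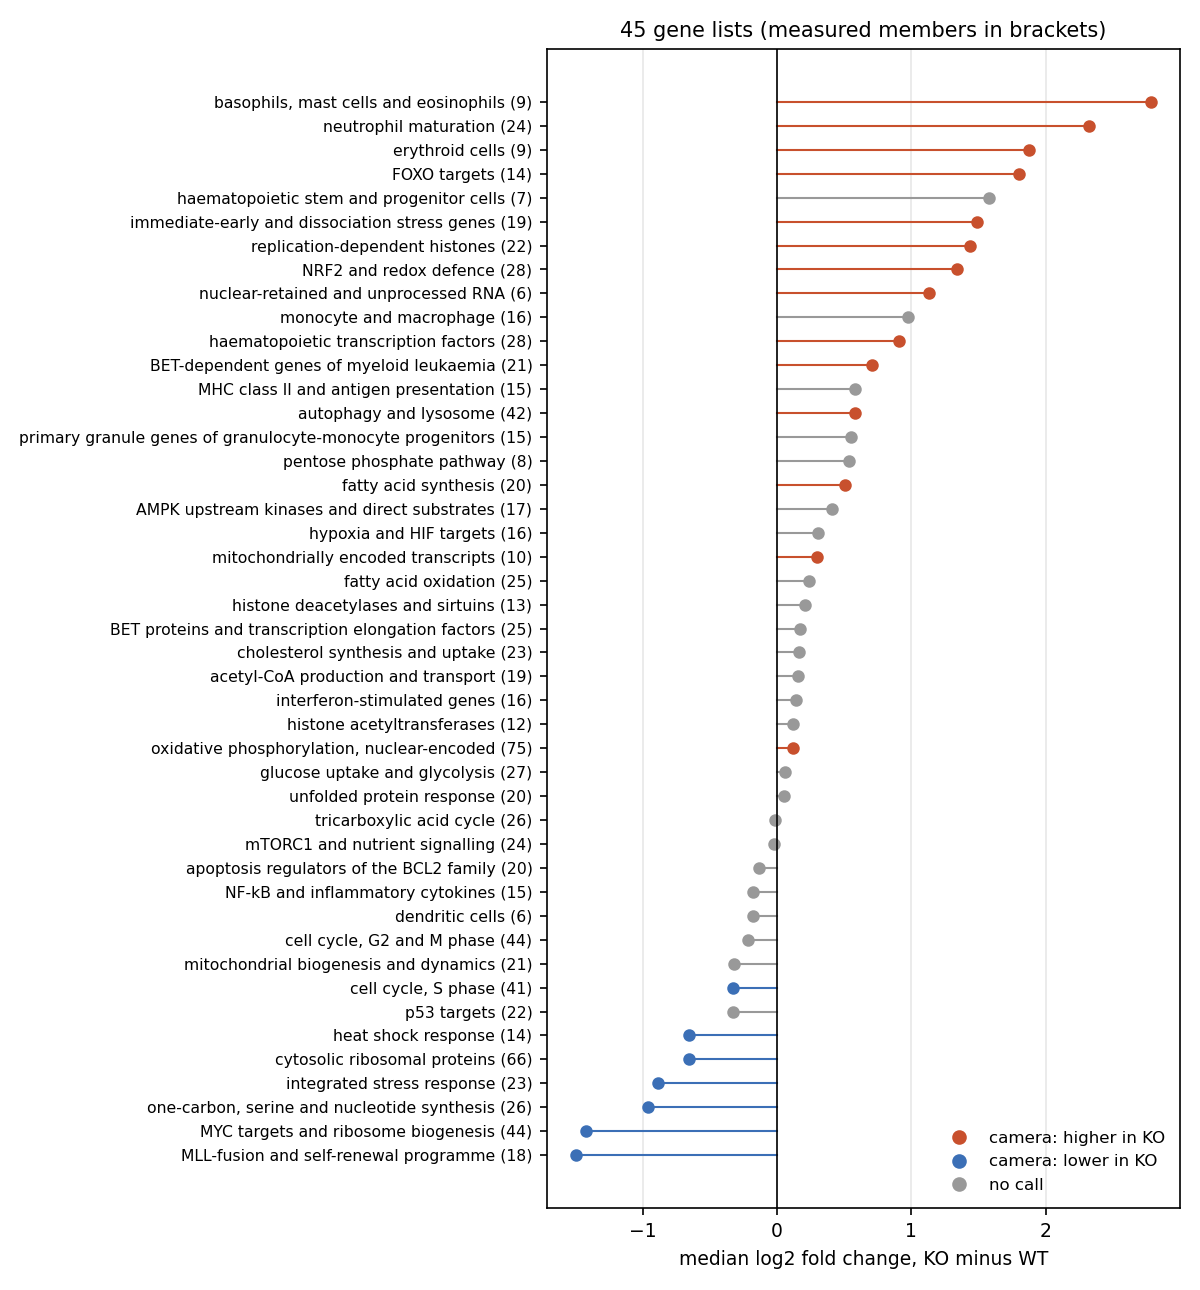
Median log2 fold change (KO minus WT, on log2(FPKM + 1)) of the 45 gene lists with at least 5 measured members, coloured by the camera call at a preset inter-gene correlation of 0.01. Of these, 14 were higher in KO and 7 lower, from a median of 2.78 for basophil, mast cell and eosinophil genes to -1.50 for the MLL-fusion programme. Medians of the oxidative phosphorylation and mitochondrially encoded lists turn negative, as do 10 of the lists without a call, with libraries rescaled to equal sums.

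Of 53 lists, 45 were tested: camera at a preset correlation of 0.01 called 14 higher and 7 lower. With a correlation estimated for each list, camera called 0 higher and 0 lower (lowest adjusted p = 0.0583), with 11 higher and 6 lower at an unadjusted p under 0.05. By contrast fry called 30 and 13. It asks only whether a list's average change differs from none, without comparing the list with other genes. With 7140 of 9108 genes called, it also passed lists split evenly, such as the unfolded protein response (9 up, 9 down, fry adjusted p = 0.000107). No list's call therefore holds in the version with an estimated correlation, and the calls rest on the preset version. The estimate was not above 0.01 for every list: it was 0.006 for MYC targets and -0.02 for neutrophil maturation. A larger correlation is therefore not why those calls were lost. For other lists it was larger, as for cytosolic ribosomal proteins (0.33) and mitochondrially encoded transcripts (0.70).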

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

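The corrections for GC content and length, alone and with the replicate block, and voom were chosen after seeing the data, and the other alternatives were planned. Between 3305 and 3595 genes were higher in KO and between 3507 and 3740 lower under the pseudocounts, quantile, loess and median-ratio scalings, variance models, corrections, voom and each library left out, against 3464 and 3676 as reported (without 1 library, 3305 to 3380 and 3507 to 3603). Counts moved by over 1.5 times with a minimum mean of 5 FPKM (2072 higher, 2383 lower), where fewer genes were tested, without a filter (5769 lower, with 4663 higher), where more were, and with libraries rescaled to equal sums (2069 higher, with 5376 lower). A mean of 0.1 FPKM gave 4632 and 5384. Median-ratio scaling moved no call, since the deposited values already carry it. With the replicate block 3420 genes were higher and 3620 lower. The numbers do not pair the libraries: deviations from the genotype means of same-numbered libraries correlated across genes at 0.00946, -0.0118 and -0.0166, and not every library correlated best with its own number. Of 4553 values of named genes under the alternatives, 4525 kept direction and side of the threshold. Rescaling to equal sums turned the log2 changes of Brd3 (-0.25), Acly (-0.39), mt-Co1 (-0.13), Xist (-0.25) and Spp1 (-0.021) negative. Brd3 and mt-Co1 went from called higher to called lower, and Acly and Xist from no call to called lower. The calls of Spp1 (adjusted p = 0.661), Tecr, Birc5 and Ifi35 ended, and quantile normalization ended that of Fth1. Acly gained a call upward with quantile (0.12) and loess (0.17) normalization, and Xist with the GC corrections (0.30, adjusted p = 0.0189 with the block) and voom (0.18). The Brd3 call was also lost with the block, with both GC corrections and without any 1 of WT replicates 1, 2 and 3 and KO replicates 1 and 3. At a pseudocount of 0.1, the log2 change of Prkaa2 was 0.10 instead of 0.01, that of Prkag3 0.09 instead of 0.01, and that of Prkab2 -0.71 (-0.24 at 0.5) instead of -0.13. Rescaling to equal sums moved Prkab2 to -0.29 and turned Prkag2 from 0.01 to -0.27. Of 1078 list values, 1011 kept direction and call. An estimated correlation left 0 lists higher and 0 lower, with adjusted p of 0.0583 for MYC, NRF2, autophagy, neutrophil and histones, 0.0672 for basophil and one-carbon, 0.0799 for transcription factors, 0.101 for FOXO, erythroid and heat shock, 0.112 for MLL-fusion and fatty acid synthesis, 0.113 for S phase, immediate-early, integrated stress and nuclear-retained, 0.215 for BET-dependent, 0.224 for ribosomal proteins, 0.562 for mitochondrially encoded, 0.598 for oxidative phosphorylation. It gave the highest adjusted p of the 24 alternatives for 20 of the 21 called lists, the BET-dependent list being the exception. fry called 30 higher and 13 lower, by a different question. It added 1.42e-07 for monocyte, 1.71e-06 for p53, 2.85e-06 for glycolysis, 4.34e-06 for BET proteins and pentose phosphate, 6.96e-06 for stem cell, 1.88e-05 for acetyl-CoA, 2.62e-05 for primary granule, 4.04e-05 for AMPK upstream, 4.17e-05 for BCL2 family and MHC, 7.05e-05 for G2/M, 7.34e-05 for fatty acid oxidation, 0.000107 for unfolded protein, 0.000125 for cholesterol, 0.000177 for mitochondrial biogenesis, 0.000773 for deacetylases, 0.00156 for hypoxia, 0.00217 for dendritic, 0.00312 for tricarboxylic acid, 0.00756 for NF-kB, and interferon at 0.000931 in the other direction. With libraries rescaled to equal sums, oxidative phosphorylation reversed (0.00864), MLL-fusion (0.0821) and mitochondrially encoded (0.451) calls ended and a monocyte call appeared (0.0368). Quantile normalization ended oxidative phosphorylation (0.543) and mitochondrially encoded (0.190), and loess ended these (0.120, 0.0663) and S phase (0.0663). A minimum mean of 5 FPKM ended BET-dependent (0.217), FOXO (0.0931) and S phase (0.0791) and left nuclear-retained RNA too few members for a test. Oxidative phosphorylation also missed the threshold without a variance trend (0.126), with array weights (0.0531), the replicate block (0.0592) and voom (0.0510). It ranged from 0.0328 to 0.0669 with 1 library left out, lost without WT replicate 1 and without KO replicate 2. The AMPK upstream list passed without a filter (0.0123), at a mean of 0.1 FPKM (0.0321), without a trend (0.0409) and with voom (0.0426). It ranged from 0.0444 to 0.0679 with 1 library left out, passing without WT replicate 2 and without KO replicate 1. The cause of these changes was not tested. Genes under 1 FPKM, among them 4 AMPK subunits, were left untested in the report. Of these subunits, Prkaa2 and Prkag3 had too few reads for depth to show a change.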

Other observations

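All tests of explanations in this part were chosen after the results were seen, and the gene values are from the planned comparison. Glycolysis genes went both ways: Pkm, the pyruvate kinase, and Gpi1 rose 2.28-fold and 2.36-fold while Ldha, the main lactate dehydrogenase subunit, fell 1.68-fold (11 up, 9 down, 7 not passing, adjusted p = 0.4555, median 0.06, -0.41 with libraries rescaled to equal sums). In the pentose phosphate pathway, Pgd, G6pdx and Taldo1 rose 2.67-fold, 2.60-fold and 1.78-fold and Prps1 fell 2.03-fold (5 up, 3 down, 0 not passing, adjusted p = 0.275, median 0.54, 0.08 with the rescaling). In the tricarboxylic acid cycle, Idh1 and Sdhc rose 2.37-fold and 1.59-fold, and Idh3a and Got2 fell 1.89-fold and 1.57-fold (9 up, 12 down, 5 not passing, adjusted p = 0.822, median -0.01, above 0 with quantile, loess and GC corrections). Of mitochondrial biogenesis genes, Ucp2 rose 2.16-fold and Tomm20, Timm23 and Pprc1 fell 2.21-fold, 1.67-fold and 8.62-fold (7 up, 12 down, 2 not passing, adjusted p = 0.508). Fatty acid oxidation genes included Acadvl and Acaa1a, up 1.82-fold and 2.15-fold, and Acsl5 and Eci2, down 2.31-fold and 2.02-fold (14 up, 6 down, 5 not passing, adjusted p = 0.246, median 0.24, -0.21 with the rescaling). Of cholesterol genes Mvd, Sqle and Stard4 rose 2.54-fold, 1.88-fold and 1.76-fold (11 up, 5 down, 7 not passing, adjusted p = 0.248, median 0.16, -0.29 with the rescaling). In the unfolded protein response, Xbp1, Calr, Edem1 and Edem2 rose 2.29-fold, 2.71-fold, 2.64-fold and 2.40-fold (9 up, 9 down, 2 not passing, adjusted p = 0.758, median 0.05, -0.41 with the rescaling and below 0 with the GC correction). Among p53 targets, Cdkn1a, the cell cycle inhibitor p21, rose 2.22-fold, and Phlda3, Pmaip1 and Trp53 itself fell 4.57-fold, 5.81-fold and 1.89-fold (7 up, 13 down, 2 not passing, adjusted p = 0.246, 14 down adjusted over the list alone). Hypoxia targets split between Ndrg1 and Bnip3l, up 13.9-fold and 4.73-fold, and Stc2 and Car12, down 48.8-fold and 4.35-fold (9 up, 4 down, 3 not passing, adjusted p = 0.351, median 0.30, -0.15 with the rescaling). Of mTORC1 signalling genes, Lamtor1 and Lamtor4 rose 1.70-fold and 1.72-fold and Lamtor3 fell 1.91-fold (8 up, 8 down, 8 not passing, adjusted p = 0.993). In G2 and M phase, Ccnb2 and Ube2c fell 1.63-fold and 1.52-fold and Cdca3 and Birc5 rose 1.54-fold and 1.41-fold, the Birc5 call being lost with the rescaling (11 up, 23 down, 10 not passing, adjusted p = 0.351). For the BCL2 family, Bcl2l11 (BIM) rose 9.15-fold and Bcl2a1a and Bid fell 18.3-fold and 1.62-fold (7 up, 8 down, 5 not passing, adjusted p = 0.633). Apart from p53 targets, counts adjusted over the list alone equalled these.

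Immune and cell type lists without a call were also mixed. Interferon-stimulated genes included Gbp3 and Oas1a, down 122-fold and 2.95-fold, and Lgals3bp and Ifi35, up 2.01-fold and 1.43-fold, the Ifi35 call being lost with libraries rescaled to equal sums (7 up, 6 down, 3 not passing, adjusted p = 0.917, 7 down adjusted over the list alone, median 0.14 but mean -0.17, and median -0.26 with the rescaling). Of NF-kB genes and cytokines, Nfkbia rose 5.0-fold and Ccl9 and Clec4e fell 38.7-fold and 18.0-fold (7 up, 7 down, 1 not passing, adjusted p = 0.864, median -0.18 although the test leans upward). Cd74, the MHC class II invariant chain, rose 42.1-fold, H2-D1 and H2-K1 2.72-fold and 2.35-fold, and H2-DMb1 fell 8.78-fold (8 up, 7 down, 0 not passing, adjusted p = 0.4555, median 0.58, 0.15 with the rescaling). Of monocyte genes Lgals3 rose 8.29-fold and Ly6c2 fell 3.50-fold (9 up, 6 down, 1 not passing, adjusted p = 0.307, median 0.97, and called higher with the rescaling at 0.62, adjusted p = 0.0368). Cd34, a surface marker of progenitors, fell 7.93-fold from 27.8 ± 0.840 to 3.51 ± 0.157 FPKM, and Cd9 and Egfl7 rose 6.48-fold and 3.21-fold (4 up, 3 down, 0 not passing, adjusted p = 0.525). Among dendritic cell genes Id2 rose 14.9-fold and Tcf4 fell 6.52-fold (3 up, 3 down, 0 not passing, adjusted p = 0.917, median -0.18 although the test leans upward). Lists with fewer than 5 measured members were not tested: for megakaryocytes Pf4 rose 2.38-fold, Plek and Gng11 fell 4.02-fold and 4.51-fold and F2rl2, with no KO read, was at least 450.0-fold lower. For T cells Lat rose 3.99-fold and Lck fell 3.66-fold, for B cells Ighm rose 1.61-fold and Cd79b and Vpreb3 fell 22.0-fold and 3.38-fold, and for natural killer cells Nkg7 rose 2.16-fold and Ccl5, with no WT read, was at least 41.9-fold higher. Of endothelial genes Egfl7 rose, Eng, with no WT read, was at least 143-fold higher and Pecam1 fell in the ratio 546-fold, interval 97.6 to 21585. Of stromal genes Runx2 fell 5.15-fold and Spp1 rose 1.36-fold, but Spp1 had no call with the rescaling (log2 change -0.02). The sex-linked list had Xist alone, given in the report.

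The 6 libraries split into 3 and 3 in 10 ways, of which 1, the real one, called 7140 genes, and the highest count among the other splits was 0 by limma (24 to 46 genes at an unadjusted p under 0.05). That is too few splits for a share under 0.05.

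Replicates of a genotype were very close. After counting noise was removed, the coefficient of variation between replicates in the most deeply read genes lay between 0.67 and 2.16%, which fits replicates that share 1 source of cells or cDNA. The labels name no source, and a biological explanation, leukaemias that are alike between mice, was not tested. If the replicates share a source, the difference between genotypes may hold the difference between 1 leukaemia and another.

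The near absence of Hoxa transcripts in KO has several candidate explanations. Partial admixture of cells that lack the programme had no test apart from the pattern itself. The summed FPKM of the set (Hoxa5, Hoxa7, Hoxa9 and Hoxa10) was 1.20 to 1.87% of the WT mean in the KO libraries. This restates the fall, and shows only that such cells would have to replace nearly all others. For the MLL-fusion list as a whole, GC content or gene length as the whole cause is argued against, since its median log2 change stayed at -1.44 after correction. That median covers the list and was not taken over the Hoxa genes alone. A different cell source behind the KO libraries, such as another leukaemia clone, cannot be told apart from an effect of AMPK loss, because the labels name 0 sources per genotype. Loss of AMPK, the biological explanation that the design gives, may reduce the programme, and stays open beside it.

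The rise of S100 and neutrophil maturation transcripts was weighed likewise. Mature neutrophils in the KO sort were examined through 9 abundant transcripts of such cells (Retnlg, Mmp9, Cxcr2, Il1b, Ly6g, Csf3r, Itgam, Camp and G0s2). Their median KO level was 0.837 FPKM, while S100a8 stood at 52072. The 9 were chosen after their values were seen, so this low level cannot decide the question. Less mature neutrophils were not examined. Of these 9 genes, 7 are also in the neutrophil maturation list, and Camp (10.3 FPKM in KO) and G0s2 (19.6) were the most abundant. With libraries rescaled to equal sums, the median log2 change of the neutrophil list was 2.40. That rescaling moved the median of all genes only from -0.02 to -0.45, so it could not have removed such a rise. It shows only that a scaling difference of that size is too small to account for the rise. Separate basophil, eosinophil or erythroid-lineage cells in the KO sort cannot be told apart from such transcripts within leukaemia cells in bulk libraries: 20 of the 47 members of these lists lay at 1 FPKM or more in KO, against 10 in WT. A leukaemia that matures further without AMPK may also account for the rise, which stays open. The low level of the 9 transcripts would bear on full maturation of the leukaemia as well.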
